A study of Homo sapiens with 3 samples.

How the data were processed

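The data were 3 libraries from HEK 293 cells. They comprise DICER ChIP-seq in wild-type cells and dsRNA sequencing in wild-type and in Dicer knockdown cells. Groups were taken from the sample labels, with 1 library per group, so there is no replicate error and no paired or replicate-based test. Per the labels' protocols, dsRNA was what remained of total RNA after T1 nuclease digestion, sequenced as paired ends on a HiSeq instrument, and the ChIP library was sequenced on a Genome Analyzer instrument.

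Per the submitters' processing notes, the ChIP data name Bowtie 0.12.7, MACS 1.4 and the hg19 build, and the dsRNA data name bcl2fastq 1.8.4, BWA 0.7 and the hg19 build. How regions of dsRNA were called, and how reads with several genomic matches were placed, is not given in the sources used here. The deposited peak list gives positions and a score per peak, which is the authors' own and was used only to rank and filter peaks. No peak scored below 100, while the peak numbers in the names run to 1955, so the 119 listed peaks are a part of that numbering. Why the others are absent is not given in the sources used here. The deposited dsRNA sheets give start, stop and summit, a coverage signal as the whole-number height of each region, not normalized by library size. Regions with a summit of 1 were most often 51 bp wide. The deposited final set gives positions with no value. The dsRNA workbooks attached to the 2 dsRNA samples are identical, so 1 copy was used and the sheet names normal and induced were read as wild type and knockdown. If that reading is wrong, every direction reverses.

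Because the sheets hold only paired regions, the sum of summits is not the depth of a library. For the main ratio, knockdown summits were scaled to the wild-type sum of summits (factor 0.958), a pseudocount of 1 was added and the log2 ratio was taken, so ratios of low regions are understated. Regions with a combined summit of 20 or more entered the counts of 2-fold differences. Medians carry 95% intervals from binomial order statistics and shares carry exact binomial intervals. Both cover counting error or the spread over regions only. Overlap means 1 bp or more. Peak overlap was compared with 10000 random placements of the same widths on the same chromosome, and with shifts of 10 to 500 kb. Peak positions are printed counting from 1.

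No hg19 annotation was used here. The RefSeq gene table given is of GRCh38.p14, so none of its coordinates were printed or converted. It served for names and for the order and spacing of neighbouring small RNA genes. Small RNA genes up to 450 bp long were joined into clusters at gaps of up to 100 kb. Each spacing pattern was slid along the dsRNA regions with a mean summit of 100 or more, with a tolerance of 10 bp. A cluster was accepted when 5 or more genes fell in regions and any other place took at most 0.5 times as many. Of 196 clusters, 18 were accepted, and 0 of the 196 mirrored patterns. This rule was chosen after about 9 settings had been looked at with their mirrored counts, so the 0 is partly a result of that choice. Over the 20 settings then tabulated, the stricter rule accepted 0 or 1 mirrored patterns and a looser rule 4 to 8. The 5S rRNA array was placed by a separate rule, also set after seeing the data. Its spacing is periodic (median 2234 bp between regions), so its mirrored pattern fits as well, and its copies were not named singly. Counted by chromosome, the tRNA genes on chromosome 11 were placed under the fewest settings: their cluster was placed only at the minimum mean summit of 100, and not at 20, 50, 500 or 1000, and its best other place took 4 genes against 8. Other clusters were also lost at some settings. In all, 193 tRNA, 22 snoRNA, 5 snRNA and 17 5S array regions were named. A few other loci were named from general knowledge of hg19, as said beside each.

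The 11 fixed gene lists were small structured RNA, snoRNA and scaRNA, microRNA genes, mitochondrial genes, replication-dependent histones, nuclear lncRNA, interferon-stimulated and dsRNA sensor genes, small-RNA pathway genes, ribosomal protein and translation genes, housekeeping genes, and apoptosis and DNA damage genes. They could be used only where members were named, which gave 1, 7 and then 0 for each of the other 9. A list's median was compared with 10000 random lists in which each member was replaced by 1 of the 200 regions nearest in mean level. The tRNA, 5S array and DICER-peak classes were formed after seeing the data.

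The rule for named items, set before the data were examined, took the 10 peaks with the highest score, up to 10 peaks by score that overlap dsRNA regions, and the 10 longest regions of the final set, which gives no value of its own. It also took the 10 highest and 10 lowest ratios at or above the median level, up to 4 members per fixed list by level, and DICER1 if it had a value. Only some of each group are printed. Items outside the rule are said to be chosen after their values were seen.

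The list comparison was tested on simulated values for the 35876 regions. Shifts of 0.25 and 0.5 planted in 200 regions came back as 0.23 and 0.48, and 11 of 200 lists without a shift fell outside the central 95%. Where simulated values rose with width, a list of wide regions was at the 100th percentile matched on level and the 94th matched on both. Matching on level alone therefore does not guard against an effect of width. Of 100 planted clusters, 100 were placed correctly. The planted clusters kept most of their genes among regions at random positions. Sparse or borderline placements, such as 11 of 31 genes, or 10 genes against 5 at the best other place, were not covered. Alternatives tried were other scalings, pseudocounts, minimum levels, overlap distances, peak scores, widths and matching, and settings of the naming. Peak position relative to genes was planned and not run. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.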

Results

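The series profiled HEK 293 cells, a human embryonic kidney cell line, with 3 libraries in 3 groups of 1 library each. DICER chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in wild-type cells and gave a list of 119 peaks. Double-stranded RNA (dsRNA), the RNA left after digestion with the nuclease T1, was sequenced from wild-type cells and from Dicer knockdown cells. DICER is the ribonuclease that cuts dsRNA and microRNA precursors into short RNAs. Each dsRNA library was deposited as a list of 271645 regions, each with a summit, the whole-number height of the read coverage. The sheet named normal was read as wild type and the sheet named induced as knockdown, by these names alone, because the same workbook is attached to both samples. There were no replicates, so every ratio compares these 2 libraries and not the conditions, and no p-value was computed between them. The total number of reads per library is unknown. All coordinates are in hg19. Those of dsRNA regions are printed as deposited, since whether they count from 0 or 1 is not given in the sources used here. No value for DICER1 itself was used here, so the knockdown was not checked.

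The first question was how much dsRNA each library held. The 2 region lists were paired, row by row: 270153 pairs overlapped and the remaining 1492 touched end to end, so regions seen in 1 library alone were not analysed here. The regions covered 23.1 Mb in wild type and 20.8 Mb in knockdown, with a median width of 62 bp and 55 bp. Summits added up to 80502410 in wild type and 84057405 in knockdown, a mean of 296 and 309 per region. Most regions were low, with a median summit of 3 in wild type and 2 in knockdown. A small number of loci held nearly all of the signal. The highest region, at chromosome 17, 33478098 to 33478381, held 6.96% of the summed height in wild type and 9.56% in knockdown, and the 10 highest regions held 28.6% and 32.2%. Regions at named small RNA loci were among the highest. By general knowledge of hg19, and not from an annotation used here, chromosome 6, 52860400 to 52860757, is RN7SK, the 7SK RNA that restrains transcription elongation. Its summit was 1651471 in wild type and 1601602 in knockdown. In the same way, chromosome 5, 140098485 to 140098671, is a vault RNA gene, VTRNA1-2, with 1511983 in wild type and 3138693 in knockdown, 1.99-fold higher after scaling. These 3 loci were singled out after their values were seen.

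The second comparison set knockdown against wild type, the comparison the design implies for the effect of losing DICER on dsRNA. Among the 35876 regions with a combined summit of 20 or more, the median log2 ratio of knockdown to wild type was -0.53 (95% interval -0.54 to -0.51 over regions, which are not replicates), a fold of 0.694. Of these, 1819 were higher by 2-fold or more and 11049 were lower by 2-fold or more. The ratio differed with level, without a steady rise. Over all regions, its median was -0.04 at a mean summit of 1 to below 3 (123233 regions, the largest class) and -0.78 at 3 to below 10. These 2 medians are ties of small whole-number heights, with intervals of no width, and unscaled they were 0 and -0.74. The median was -0.68 at 10 to below 30, a class with 24559 of the 35876 regions. It was -0.41 at 30 to below 100, -0.16 at 300 to below 1000, 0.14 at 3000 to below 10000 and -0.02 at 10000 or more. The scaling decided part of this. The median over the 35876 regions was -0.28 scaled to the median ratio and -0.054 with sums without the highest 1%. Scaling to the median ratio in place of the summed summits raised the scaling factor by 0.26 log2 units, with a smaller rise in the ratios of low regions because of the pseudocount, and gave 2808 higher and 8457 lower regions. Leaving the highest 1% of regions out of the sums raised the factor by 0.49 log2 units and gave 4133 higher and 6609 lower. With these reduced sums the medians of all classes from a mean summit of 30 were above 0, so the direction of the classes with a decrease there rests on the scaling, as does that of the lowest class (0.23). The classes at 3 to below 10 and 10 to below 30 stayed below 0 under each of the 4 scalings. The class at 3000 to below 10000 was above 0 under all 4, but the main scaling gives the lowest ratios of the 4, so the others could not have lowered it.

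**Figure D1:**
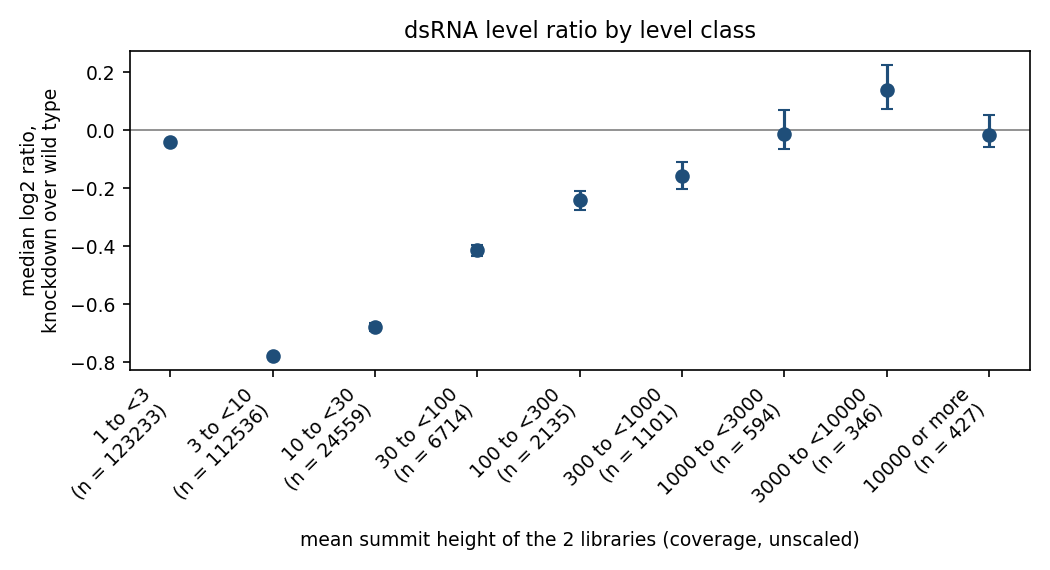
Median log2 ratio of knockdown to wild-type summit (vertical axis) in 9 classes of mean summit height (horizontal axis, unscaled coverage), with n regions per class, scaled to the summed summits. Bars are 95% intervals of the median over regions. The median lies at -0.04 for a mean summit of 1 to below 3, at -0.78 for 3 to below 10 and at 0.14 for 3000 to below 10000. Below a mean summit of 10 the medians are ties of small whole-number heights, so the intervals have no width.

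Among regions at or above the median level, the 10 highest ratios were 13.6-fold to 27.6-fold and the 10 lowest were 22.6-fold to 253-fold lower in knockdown. Most of both rested on low heights: 7 of the 10 highest ratios had a wild-type summit under 10, and 8 of the 10 lowest had a knockdown summit under 10. The region at chromosome 5, 3508877 to 3508949, had a summit of 131 in wild type and 3277 in knockdown. The region at chromosome 5, 170955862 to 170955909, had 44 and 1297. In the other direction, the region at chromosome 1, 62390855 to 62390945, had 3986 in wild type and 34 in knockdown, and that at chromosome 11, 5327500 to 5327535, had 736 and 2. None of these 20 regions overlapped a DICER peak, and no gene name was assigned to them.

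The third result was the deposited final set, labelled induced, of 1003 regions. Each of its rows equalled a region of the knockdown list, and the set was exactly the 1003 regions with a summit above 1500 in both libraries. A further 137 regions passed that height in knockdown alone and 75 in wild type alone, and none of these was in the set. The set held 96.0% of the summed height in wild type and 96.7% in knockdown. How many of its regions were higher in knockdown rests on the scaling. Scaled to the sums, 523 of the 1003 were higher (52.1%, exact 95% interval 49.0% to 55.3%) and 480 were lower. Since the set makes up nearly all of those sums, this scaling holds its summed height about equal in the 2 libraries. This split therefore does not decide whether the set was higher. With this scaling the median log2 ratio was 0.03 (95% interval -0.02 to 0.07). By 2-fold or more, 68 regions were higher and 24 lower. The higher regions numbered 570 unscaled, 725 when scaled to the median ratio and 871 with the sums taken without the highest 1% of regions. The highest ratio was at chromosome 5, 93905085 to 93905248, with a summit of 9240 in wild type and 52071 in knockdown (5.40-fold). The lowest was at chromosome 20, 26188994 to 26189108, with 19079 and 2796 (7.12-fold lower). The 10 longest regions of the set were 1113 to 5864 bp, with ratios between 0.442 and 1.05. The longest, at chromosome 1, 564450 to 570314, had a summit of 50133 in wild type and 53455 in knockdown. By general knowledge of hg19 that interval is a nuclear copy of mitochondrial DNA. The region lists hold no mitochondrial chromosome.

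The fourth comparison grouped regions by the small RNA genes they cover. Names came from matching the spacing of neighbouring small RNA genes to the spacing of regions, which named 237 regions without use of their ratios. The 193 regions at tRNA genes were higher in knockdown, with a median log2 ratio of 0.56 (95% interval 0.51 to 0.67), a fold of 1.48. Of these, 172 were higher and 21 lower, and 32 against 2 by 2-fold or more. This median was above all 10000 random lists of regions of similar level, whose median was -0.11. Those lists drew regions singly, while tRNA genes may share reads, so the interval and this comparison may overstate the certainty. The tRNA median was 0.56 to 1.05 over the scalings tried. The main scaling gives the lowest ratios of these, so the others could only raise the median. It was 0.55 without the 8 regions of the chromosome 11 cluster, which was placed at only 1 of the 5 minimum summits tried. The tRNA genes were grouped after some of their ratios had been seen, so this class is not a planned test. The valine tRNA gene TRV-CAC2-1, at chromosome 6, 27248018 to 27248144, had a summit of 4273 in wild type and 16284 in knockdown (3.65-fold). The cysteine tRNA gene TRC-GCA1-1, at chromosome 7, 149007257 to 149007439, had 19763 and 37293 (1.81-fold). The aspartate tRNA gene TRD-GTC3-1, at chromosome 6, 27551139 to 27551333, went the other way, with 106213 and 54624. The 4 named genes of its family had a median log2 ratio of -0.94. The highest tRNA region, the valine gene TRV-CAC8-1 at chromosome 1, 149294574 to 149294762, differed little, with 1390664 and 1564634 (1.08-fold). The next highest, TRH-GTG1-4 and TRG-GCC2-6, were 1.04-fold and 1.10-fold. The class median counts each region alike, so it does not describe the summed tRNA height. These genes were chosen after their values were seen, and the names of both valine genes were given only with clusters joined at gaps of up to 100 kb, not 30 kb. Many tRNA genes have near-identical copies, so reads may have been assigned to the wrong copy.

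The medians of the other small RNA classes lay within the central 95% of lists of similar level. Of the list of snoRNA and scaRNA genes fixed before the data were examined, which guide RNA modification or processing, 7 of 31 could be named. Their median log2 ratio was 0.09, at the 76.3rd percentile of random lists of similar level, the 97.0th of lists of similar width and the 61.3rd of lists matched on both. The 7 were the U3 genes SNORD3A, SNORD3B-1, SNORD3B-2 and SNORD3C, with SNORA73A, SNORA73B and SNORD118. Genes for the same RNA may share reads, so these are not 7 separate measurements. The U3 gene SNORD3C (chromosome 17, 19092911 to 19093571) had a summit of 379040 in wild type and 393298 in knockdown, and SNORD3A (chromosome 17, 19091312 to 19091899) had 114637 and 127455. The U8 gene SNORD118 (chromosome 17, 8076539 to 8076915) had 104582 and 154635, and SNORD3B-2 (chromosome 17, 18967050 to 18967476) had 35468 and 30661. The list of small structured RNAs had 1 of 30 named, the minor spliceosome RNA RNU11 (chromosome 1, 28975106 to 28975512), with 11385 and 20879 (1.76-fold). The 17 copies of the 5S ribosomal RNA array on chromosome 1 had a median log2 ratio of -0.15, at the 25.7th percentile of lists of similar level, the 94.4th of lists of similar width and the 4.11th of lists matched on both. That sign flips to 0.11 when scaled to the median ratio and to 0.35 when the highest 1% of regions is left out of the sums. The near-identical copies may share reads, so they are not 17 separate measurements. Each copy had a mean summit of 668322 or more, while only 427 regions in all reached 10000. The lists of similar level therefore reached below the array. Those matched on both came from pools of 600 regions that reached below 10000. The other 9 fixed lists had 0 members that could be named and were not tested.

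**Figure D2:**
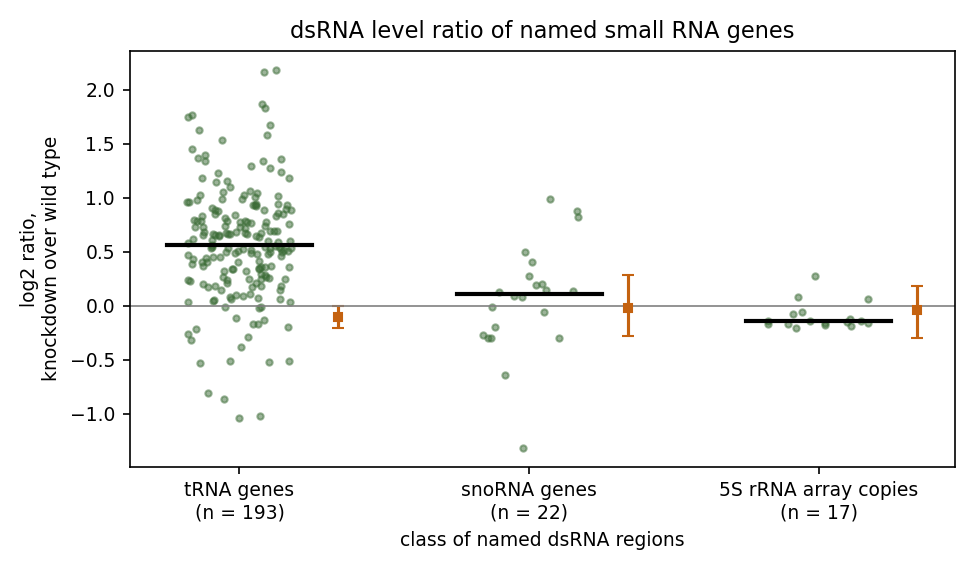
Log2 ratio of knockdown to wild-type summit (vertical axis) for regions named as tRNA genes, snoRNA genes and copies of the 5S rRNA array (horizontal axis). Green points are regions, placed sideways at random, black lines are class medians, and orange squares with bars are the median and central 95% of 10000 lists of similar level; the tRNA median of 0.56 lies above its bar.

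The last comparison asked whether DICER-bound sites lie at dsRNA regions. The 119 peaks had a median width of 368 bp and carried the authors' peak score, with a median of 127.0 and a maximum of 1054. Of the 118 peaks outside the mitochondrial chromosome, 77 overlapped a dsRNA region (65.3%, exact 95% interval 55.9% to 73.8%). Random placements on the same chromosomes gave a mean of 5.40 and at most 17 in 10000 placements. The final set was overlapped by 48 peaks (40.7%, exact 95% interval 31.7% to 50.1%), against a mean of 0.0300 and at most 2 in the placements. A DICER peak lay at 51 of the 1003 regions of the final set (5.08%) and at 64 of the 270642 other regions (0.0236%). The share rose with level, from 0.0122% (15 of 123233) at a mean summit of 1 to below 3 to 8.67% (37 of 427) at 10000 or more, with exact 95% intervals of 0.00681% to 0.0201% and 6.17% to 11.7%. No input or control ChIP library was analysed here.

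**Figure D3:**
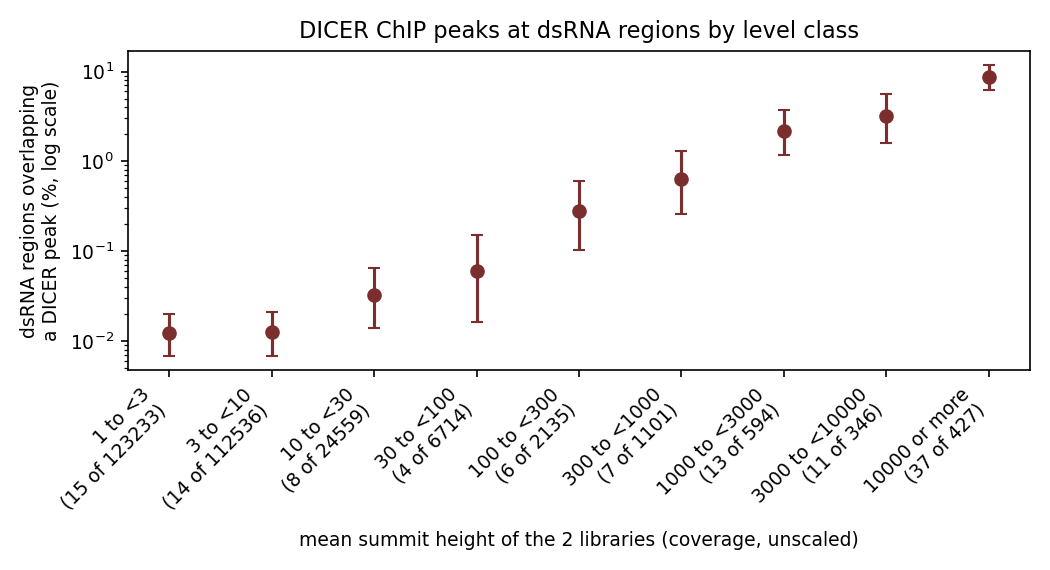
Share of dsRNA regions that overlap a DICER peak (vertical axis, percent on a log scale) in 9 classes of mean summit height (horizontal axis, unscaled coverage), with the number of regions under each class. Bars are exact 95% binomial intervals; the share is 0.0122% in the lowest class and 8.67% in the highest.

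The highest-scoring peak, with a score of 1054, was at chromosome 1, 121483981 to 121485598, and overlapped 5 dsRNA regions, the highest with summits of 17 in wild type and 35 in knockdown. The peak ranked next, at chromosome 7, 5566156 to 5566639, scored 922.6 and overlapped no dsRNA region. By general knowledge of hg19 it lies beside ACTB, the gene for beta-actin. The peak at chromosome 21, 9825303 to 9828069 (score 729.5), overlapped a region with summits of 1211939 and 1020966. Peaks at chromosome 1, 91852622 to 91853272 (score 429.8), and chromosome 12, 20704355 to 20704656 (score 393), overlapped regions with wild-type summits of 553265 and 586440. The peak at chromosome 17, 33477963 to 33478713 (score 376.2), covered the highest dsRNA region. Among the 10 highest-scoring peaks, 8 overlapped a dsRNA region and 5 the final set. No annotation of repeats was used, so which of these peaks lie at repeated sequence was not checked. Of the 10 highest-scoring peaks with a dsRNA region, 3 had a higher summit in knockdown at their highest region, 6 a lower and 1 an equal summit, before scaling, but 6 were higher and 4 lower with the highest 1% of regions left out of the sums. Over all 77 peaks with a dsRNA region, 51 were higher, 24 lower and 2 equal before scaling, 49 were higher and 28 lower after scaling to the sums, and 64 were higher and 13 lower with the reduced sums. There were 7 peaks whose highest region was a named tRNA gene. Across the 86 regions at peaks with a combined summit of 20 or more, the median log2 ratio was 0.12 (95% interval -0.06 to 0.34), at the 99.5th percentile of lists of similar level and at the 96.2nd when width was matched too. For those with a mean summit of 100 or more, the median was 0.18 at the 99.6th percentile, and 0.11 at the 95.2nd without the named tRNA genes, inside the central 95%. The regions at peaks went both ways: of the 86, 10 were higher and 14 lower by 2-fold or more, scaled to the sums. In the final set, a DICER peak lay at 5 of the 10 regions with the lowest ratios and at 0 of the 10 with the highest. These regions were picked after their values were seen, and the difference was not tested. Their levels differed too. Wild-type summits were 7361 to 229596 at the lowest ratios and 1710 to 9240 at the highest, and knockdown summits 2796 to 85829 and 6100 to 52071. The share of regions with a peak rises with level. Whether the regions at peaks share repeated sequence was not checked.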

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

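The settings for peak midpoints, for regions at or above the median level in the ratio, for the final set's directions, for matching on width as well as level, for naming tRNA genes and for the unscaled and reduced sums in the gene classes were chosen after seeing the data. Of 82 alternative values, 56 stayed within the range set for them. That count is not a measure of stability, since it takes in percentiles that moved far. The percentile of the 5S array went from 25.7 to 94.4 matched on width and 4.11 matched on level and width. Scaling is a limit, since a few regions hold most of the height and the depth of each library is unknown. No paired analysis was possible because each group has 1 library. Alternatives that need genes of hg19 (peak midpoint in a gene, gene body with 5 kb on each side) were not run, and strand was not given. The cause of the changes below was not tested, except where fewer regions or peaks were counted by construction.

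With fewer items by construction, 60 of the 119 peaks were at or above the median score, 48 of these overlapped a dsRNA region (mean of random placements 3.02), and 51 peak midpoints lay inside a region (placements 1.16). Pairs with both regions 50 bp or wider numbered 180474, and 148412 were at or above the median level. The median log2 ratio was -0.28 when scaled to the median ratio, -0.054 with sums without the highest 1%, -0.47 unscaled, -0.21 at a combined summit of 100 or more, and -0.72 at or above the median level. Regions higher by 2-fold or more were 2808, 4133, 459 and 9131 for the median ratio, the reduced sums, the combined summit of 100 and the median level. Regions lower by 2-fold or more were 6609, 911 and 50583 for the last 3 of these. In the final set, 871 regions were higher with the reduced sums. The tRNA median was 0.82 and 1.05 with the median ratio and the reduced sums, the regions at DICER peaks 0.37 and 0.60, and the fixed snoRNA list 0.58 with the reduced sums. The 5S array reversed, to 0.11 and 0.35. The regions at DICER peaks fell to the 96.2nd percentile when matched on level and width.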

Other observations

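The random placements were planned, but the threshold for reading them was set after the results were seen. The tests of multi-copy reads, of depth and of the tRNA regions were chosen after the results were seen. The test of shifted peaks was set before. DICER peaks also lay at 2 further loci that general knowledge of hg19 places at small RNA genes, picked after their values were seen. The peak at chromosome 9, 35657673 to 35658032 (score 117.0), lies at RMRP, the RNA of the ribonuclease MRP, with dsRNA summits of 89226 in wild type and 64158 in knockdown. The peak at chromosome 12, 120729401 to 120729672 (score 137.9), lies at a U4 spliceosomal RNA gene, with 78950 and 104370. The 1 peak on the mitochondrial chromosome spans 1874 to 4089, where the dsRNA lists hold no regions.

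DICER peaks lay at dsRNA regions far more often than by position alone: the observed overlap was at the 100th percentile of 10000 random placements. Dense dsRNA regions around the peaks are argued against as the cause, since the overlap was 11.4 times the mean for peaks shifted by 10 to 500 kb. Reads of multi-copy sequence, placed at the same copies in both assays, remain a candidate explanation, examined here at the 5S array alone. Only 1 of the 17 near-identical copies of the 5S array held a DICER peak, though all 17 were high in dsRNA. In wild type their dsRNA summits were 690267 to 873971, apart from 1 of 1440015, as reads spread over the copies would give. The single copy with a peak decides nothing, because it is not known how ChIP reads with several matches were placed. Binding of DICER where dsRNA is made stays open and was not tested, as no control ChIP library was analysed here.

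The ratio of knockdown to wild type differed between level classes, with the lowest medians at a mean summit of 3 to below 30 and a median of -0.04 in the class below that, which turned to 0.23 with the sums taken without the highest 1% of regions. From a mean summit of 30, the sign of the classes below 0 rests on the scaling, while the class at 3000 to below 10000 was above 0 under each scaling tried. The other scalings only raise the ratios, so they could not have lowered that class. From a mean summit of 30, where the pseudocount matters little, a single difference in depth would move the level classes nearly alike, but their medians ranged over 0.55 log2 units, and the 95% intervals of the lowest and highest were separate. A different share of low-level background in the 2 libraries stays open, and so does the knockdown. Neither was tested.

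The tRNA regions were higher in knockdown than regions of similar level. The increase was not confined to a few anticodon families: 39 of 43 had a median log2 ratio above 0, and 38 of 43 without the chromosome 11 cluster. With only 21 of the 193 tRNA regions lower, most families had to be above 0, so this count is not a separate test. Effects of reads shared by near-identical copies were not tested. The width of the regions is argued against as the cause: the tRNA median was at the 100th percentile of lists matched on level and width. Whether Dicer knockdown raised the tRNA regions cannot be told apart from a difference between single libraries, with 1 dsRNA library per condition. The 10 tRNA regions at DICER peaks had a median log2 ratio of 0.71 and the 183 others 0.55, but 4 of the 10 are from the chromosome 11 cluster, which is named at only 1 of 5 minimum summits. Without that cluster the values were 0.50 over 6 regions and 0.55 over 179. The difference was not tested.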
